A study of Mus musculus with 9 samples.

How the data were processed

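RNA sequencing libraries of K7M2 cells, a mouse osteosarcoma line, were analysed from the gene table of the whole series. The table holds 55401 genes with an FPKM column and a count column for each of 9 libraries, and every column name matched 1 library's description in the labels. Libraries were grouped by their labels as untreated, platelet treated and (A/R) platelet treated, with 3 in each group. The labels do not expand A/R, and it is used here only as a name. Libraries were made from total RNA with an mRNA sequencing kit, per the labels' protocols. The genome build was GRCm38 (mm10), per the submitters' processing notes. The aligner, the counting program and the use of strand are not given in the sources used here, so overlapping genes and near-identical copies cannot be told apart by their counts. Of the 55401 gene IDs, 55141 are also in GENCODE release M21, and 51957 of those have the same chromosome, start and end there. Gene names and coordinates below are those of the deposited table.

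The FPKM values were deposited by the authors as fragments per kilobase of transcript, scaled to mapped fragments, with 0.0001 in place of 0 for genes without counts. The deposited counts are estimated counts rather than tallies of fragments, as far as the values show. In genes with a single transcript, 99.3% to 99.5% of the counts per library lay within 1% of FPKM times transcript length times 1 factor per library. Among genes with low counts, 97.5% to 97.9% equalled that product rounded up. Genes also piled up at 4 counts, where a library had 898 to 1116 genes, against 286 to 342 genes at 3 counts and 173 to 213 genes at 5 counts. It therefore appears that 1 fragment added about 4 counts. All count values were whole numbers, so no rounding was needed. Because such counts overstate the number of fragments, the gene tests and the list tests with a preset correlation were repeated with counts divided by 4. That division is 1 factor for all libraries, so it says little about stability.

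Library totals ranged from 37465049 to 61366030 counts, at about 4 counts per fragment. Genes that passed the filter held 99.4% to 99.5% of the counts. A gene without counts was given the limit that 0 fragments allow, 3 fragments or 12 counts per library, which is 0.196 to 0.320 CPM, counts scaled to the total of the library. Such limits cover counting error only, since the libraries carry no molecular identifiers. No pair of libraries within a group was a repeat deposit: the chi-square of fragment numbers per gene ranged from 9.81 to 17.4 there.

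Genes with an FPKM of at least 1 in at least 3 of the 9 libraries were tested, 11826 in all. The plan made before the data were examined named limma on log2(FPKM + 1) for a table of FPKM alone and edgeR's quasi-likelihood test for a table with counts. Since the table holds counts, edgeR 4.0.16 in R 4.3.3 was used, with TMM scaling and 1 mean per group for all 9 libraries in 1 fit without covariates. The comparisons were platelet against untreated, (A/R) platelet against untreated, and (A/R) platelet against platelet. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of the F statistic.

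Before the data were examined, 36 gene lists were fixed, covering signalling, stress, metabolism, cell cycle, matrix and the markers of platelets and other cells. Lists with at least 5 tested members were compared with all other genes by camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and adjustment over the lists. The test was repeated with the correlation estimated from the data. For single members the count of calls is also given adjusted over the list alone. Shared chance between the comparisons with the same untreated libraries was simulated in 50 sets of unchanged groups.

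The rule for naming genes was also fixed beforehand. It takes the 10 largest rises and the 10 largest falls among called genes with a mean FPKM of at least 5 in the higher group and no overlap between the groups, leaving out predicted and clone-named genes. It adds up to 3 members of each list with the smallest p, or the single smallest where none passed. It adds fixed genes in every comparison, whatever their p, among them Ppbp, Pf4, Itga2b, Tubb1, Ccn2, Tgfb1, Cd274, Vegfa, Myc, Mmp9, Il6, Ccl2, Hmox1, Mki67 and Col1a1. The text takes a part of these, some results are not reported here, and genes named outside the rule are marked as chosen after their values were seen.

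The calling was tested on simulated counts with 200 of the 11826 genes changed. Their spread was drawn from edgeR's own fit, which may favour edgeR. For platelet against untreated, edgeR recovered 24% of genes changed by 0.3 (log2), 68% at 0.5, 78% at 1 and 96% at 2, and 10 of 143 calls were false. For (A/R) platelet against untreated the shares were 16%, 42%, 74% and 88%, and 9 of 119 calls were false. DESeq2 1.42.0 made 45 false calls among 195 and 47 among 184 in these simulations.

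Alternatives planned before the data were examined were limma on log2(FPKM + 0.1) and log2(FPKM + 0.5), no filter, a filter at FPKM 5, median-of-ratios scaling, quantile normalization, a fit without a trend, a robust fit, only the 6 libraries of a comparison, a block for the replicate number, each library left out in turn, and a change of at least 2-fold. Chosen after the data were seen were limma on log2(FPKM + 1), DESeq2, counts divided by 4, and scaling by library totals alone. Pathway terms of the deposited annotation were also tested afterwards. Figures were drawn with matplotlib 3.10.9.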

Results

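The series addressed how platelets alter gene expression in K7M2, a mouse osteosarcoma cell line that forms metastases in mice. RNA was sequenced from 3 untreated libraries, 3 libraries of cells treated with mouse platelets, and 3 libraries of cells treated with mouse platelets marked (A/R), a term that the labels do not explain. The titles give 24 h for all libraries. The treatment labels instead give 24, 25 and 26 h for the platelet libraries and 27, 28 and 29 h for the (A/R) platelet libraries, rising by 1 h from sample to sample, so that hours and (A/R) are confounded as labelled. Whether these labels are true times is not known. Nothing in the labels says that the replicates were separate cultures, and p-values therefore measure the spread between these libraries, which may be technical only. Replicates 1 to 3 held 51452538, 54240592 and 37465049 counts in the untreated group. They held 51395827, 47639208 and 46142184 counts in the platelet group and 45150198, 61366030 and 59831069 counts in the (A/R) platelet group. The first principal component held 38.3% of the variance, with scores of 32.6 to 32.9 in the (A/R) platelet libraries, -15.6 to -12.1 in the platelet libraries and -19.1 to -17.5 in the untreated libraries.

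Platelets raised 25 genes and lowered 6, each by less than 2-fold. The largest rise among the named genes was that of Sema7a, a membrane-anchored semaphorin, whose FPKM was 6.36 ± 0.507 (SD, n = 3) in untreated and 11.4 ± 0.367 in platelet libraries. Among the other named rises were Dusp5, a phosphatase of ERK (log2 fold change 0.77 ± 0.097, SE), Fhl2, a LIM domain coactivator (0.72 ± 0.076), and Ccn2, connective tissue growth factor (0.64 ± 0.059). Ccn2 FPKM went from 28.4 ± 2.17 to 43.9 ± 0.922. Flcn (0.64), Nedd8 (0.62), Plaur, the urokinase receptor (0.58), Hmga2 (0.53), the matricellular gene Ccn1 (0.48) and Hbegf, a ligand of the EGF receptor (0.48), also rose. Lemd2 (-0.62), Mgat3 (-0.49), Serpinb9, an inhibitor of granzyme B (-0.48), and Denn2b (-0.38) fell, as did Afap1l2 (-0.95) and Parp9 (-0.60), which were chosen after their values were seen. In GRCm38 coordinates, Sema7a lies on the plus strand of chromosome 9 at 57940112 to 57962865 and the protein-coding Ccn2 on the plus strand of chromosome 10 at 24595442 to 24598683.

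In all, 31 of 11826 genes passed edgeR's quasi-likelihood test at an adjusted p under 0.05, with 25 higher and 6 lower, against 1524 genes at an unadjusted p under 0.05. The smallest adjusted p was 0.00529, for Hmga2 and Hbegf, and 0 genes passed edgeR's test with a fitted change of at least 2-fold. The groups did not overlap in 19.1% of genes, where chance gives 10%. The count was 18 without platelet replicate 3 (14 of them among the 31), 18 in the 6 libraries of the comparison alone (16 among the 31) and 222 with DESeq2 (all 31 included, 139 higher and 83 lower). Without platelet replicate 2 the split was 17 higher and 8 lower. Without 1 of the 9 libraries in turn, the calls of Dusp5 and Fosl1 were lost in 2 fits (highest adjusted p 0.0745 and 0.0641), of Flcn in 5 (0.0968), of Nedd8, Lemd2 and Jun in 7 (0.178, 0.151 and 0.138), of Dusp6 in 8 (0.129), and of Denn2b and Parp9 in 9 (0.187 and 0.184). Dusp5 was lost without platelet replicate 1 or 3, Fosl1 without untreated replicate 1 or 2, and Flcn without untreated replicate 1 or 3, platelet replicate 2 or 3 or (A/R) platelet replicate 1. Nedd8 kept its call only without untreated replicate 2 or (A/R) platelet replicate 2, Lemd2 only without (A/R) platelet replicate 1 or 2, Jun only without (A/R) platelet replicate 1 or 3, and Dusp6 only without untreated replicate 3.

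Of the fixed lists, immediate early genes stood out in platelet libraries. Of 20 measured members, 4 rose over all genes tested: Dusp5, Dusp6 (0.46), Fosl1 (0.38) and Jun (0.43), the last chosen after its value was seen. Adjusted over the list alone, 15 rose and 0 fell, and the list median was 0.36 (camera adjusted p 1.3e-21, and adjusted p = 0.00657 with an estimated correlation). Ribosome biogenesis genes were higher as a list with a median of 0.14 (adjusted p 6.61e-09, and adjusted p = 0.0378 with an estimated correlation). None of its 29 members passed over all genes, whereas 17 rose adjusted over the list alone. The member with the smallest p was Fbl, the nucleolar methyltransferase fibrillarin, at 0.30 (adjusted p 0.0784).

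Camera called 12 of 31 lists in this comparison, 7 higher and 5 lower (3 higher and 7 lower with quantile normalization, which kept 8 of the 12), and the remaining 10 were not called with an estimated correlation. Ribosomal proteins (35 measured, 0 passed over all genes or adjusted over the list alone, Rplp0 at 0.17) were higher as a list at an adjusted p of 6.31e-08, with adjusted p = 0.472 with an estimated correlation. Nuclear genes of oxidative phosphorylation (39 measured, 0 passed either way, Uqcrfs1 at 0.19) were higher at 0.000253, with adjusted p = 0.472 with an estimated correlation. Stress genes of ATF4 (26 measured, 0 passed, 2 higher adjusted over the list alone, Chac1 at 0.30) were higher at 0.0168, with adjusted p = 0.20 with an estimated correlation. TGF-beta targets (21 measured, 1 passed, Ccn2, and 2 adjusted over the list alone) were higher at 0.0236. The list of matrix enzymes (15 measured, 1 passed, the receptor gene Plaur, and 3 adjusted over the list alone) was higher at 0.0480. The adjusted p of these lists with an estimated correlation was 0.390 and 0.472, in that order. Interferon-stimulated genes (17 measured, 0 passed either way, Gbp7 at -0.66) were lower at 0.0126, with adjusted p = 0.165 with an estimated correlation. Collagens and matrix genes (19 measured, 0 passed, 1 higher and 2 lower adjusted over the list alone, Col5a1 at -0.32) were lower at 0.0152, and osteoblast markers (9 measured, 0 passed, 3 lower adjusted over the list alone, Col1a1 at -0.28) at 0.0175. With an estimated correlation their adjusted p was 0.595 and 0.351. Mitosis genes (30 measured, 0 passed either way, Top2a at -0.16) were lower at 0.0235 and replication genes (30 measured, 0 passed either way, Mcm10 at -0.21) at 0.0480. With an estimated correlation their adjusted p was 0.169 and 0.20. Targets of YAP were not called as a list (adjusted p 0.483), though Ccn1, Ccn2 and Ankrd1 (0.42) rose, 3 of 14 measured members. Adjusted over the list alone, 3 rose and 7 fell, and the list's median was -0.13 while its mean was 0.01 and its test pointed up. In fits without 1 of the 9 libraries, the calls of the ribosomal and oxidative phosphorylation lists held throughout. Interferon-stimulated and ATF4 genes lost theirs without platelet replicate 2 (0.0532 and 0.0566), and mitosis genes without platelet replicate 2 or untreated replicate 1 (0.0938, the latter). Collagens lost theirs without untreated replicate 1 or platelet replicate 1 (0.125, the latter), and osteoblast markers without untreated replicate 3 or platelet replicate 1 (0.212, the latter). TGF-beta targets lost theirs without platelet replicate 2 or untreated replicate 3 or 2 (0.0963, the last). Replication genes kept theirs only without untreated replicate 3, platelet replicate 1 or (A/R) platelet replicate 1 (up to 0.151 otherwise), and matrix enzymes only without platelet replicate 3 (up to 0.148 otherwise).

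The sum of transcripts that platelets themselves carry was not higher in the platelet libraries. The 26 platelet transcripts summed to 7.12 ± 1.45 CPM (SD, n = 3) in untreated, 6.70 ± 1.13 in platelet and 5.93 ± 0.333 in (A/R) platelet libraries. Ppbp, which encodes pro-platelet basic protein, was 0.29 lower on the log2 scale with platelets (edgeR adjusted p 0.622). Since Ppbp alone already held 3.26 to 4.33 CPM in untreated libraries, the sum would miss small amounts of platelet RNA. Gp5, a platelet transcript chosen after its values were seen, had 0 counts in the 3 untreated libraries. It held 8, 6 and 4 counts in platelet and 8, 16 and 3 in (A/R) platelet libraries, few fragments at about 4 counts each. F13a1 went the other way, with 14, 0 and 0 counts in untreated and 0 in each platelet library. Tubb1 had 0 counts in all 9 libraries, which allows up to 0.320 CPM in the library with the fewest counts. Pf4 held 0 to 17 counts and Itga2b 0 to 32 counts per library. Among other genes fixed for every comparison, the values were 0.24 for Myc (adjusted p 0.360), 0.19 for Tgfb1 (0.387), -0.21 for Mki67 (0.320) and -0.08 for Ccl2 (0.580). Vegfa (-0.01), Hmox1 (-0.04), Mmp9 (-0.04) and Cd274 (0.07) had adjusted p of 0.791 to 0.990, and none of these 8 genes passed.

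**Figure D1:**
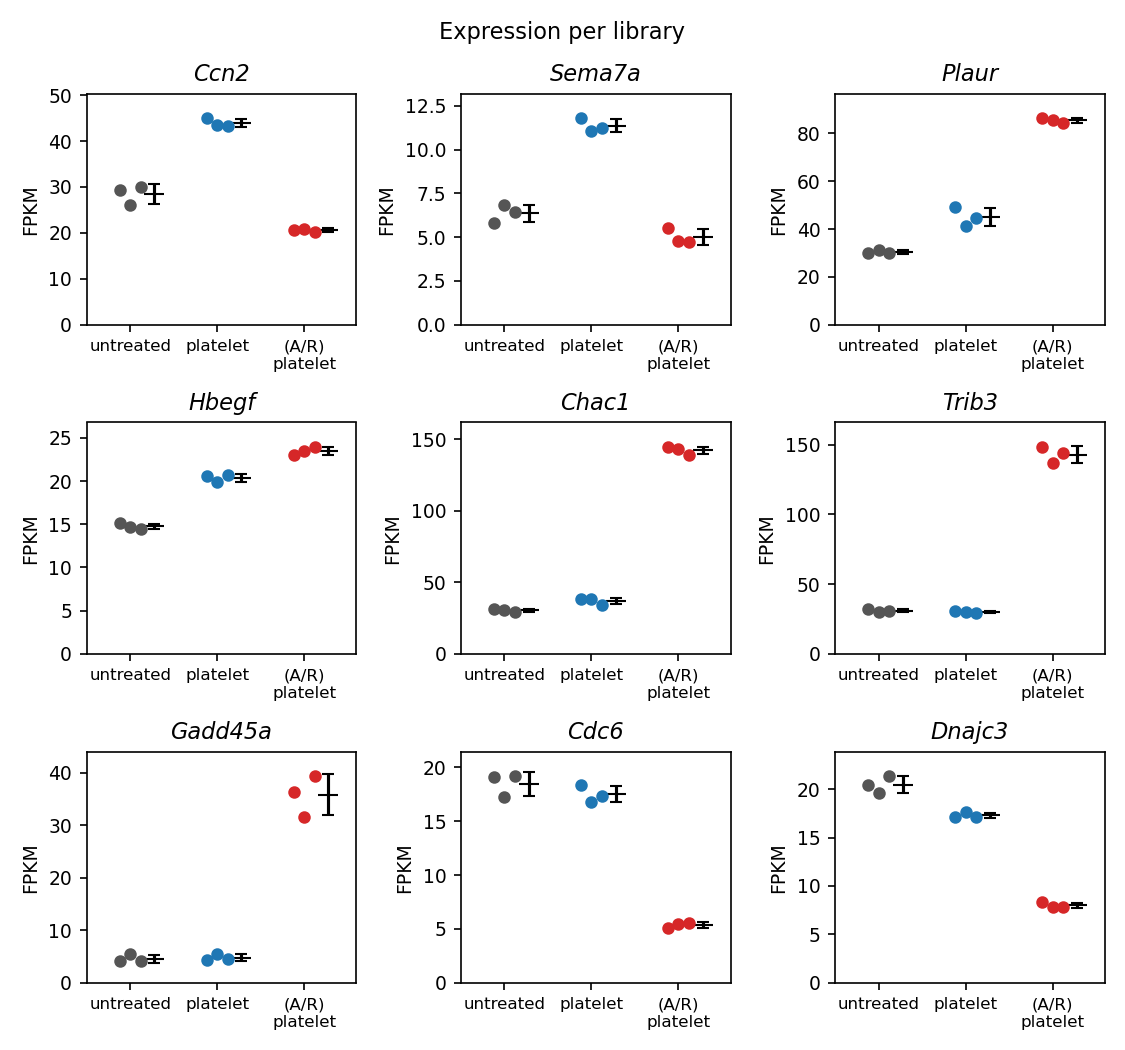
FPKM of 9 genes in each library (points) of the untreated, platelet and (A/R) platelet groups, with the mean and SD of 3 libraries beside them (bars); each vertical axis starts at 0. Ccn2 was highest in platelet libraries (43.9 ± 0.922), while Chac1 was 142 ± 2.64 in (A/R) platelet libraries against 30.3 ± 1.13 in untreated ones.

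Cells treated with (A/R) platelets differed widely from untreated cells, and several stress genes were among the named rises. Stbd1, a glycogen-binding protein, rose 10.5-fold from 1.61 ± 0.330 to 16.4 ± 1.13 FPKM (SD, n = 3). Angptl6 rose 9.37-fold and Gadd45a, a growth arrest gene, 8.0-fold. Cth, cystathionine gamma-lyase, rose 5.38-fold, Gtpbp2 5.00-fold, Gdf15, a stress-induced cytokine, 4.96-fold, and Chac1, which degrades glutathione, 4.86-fold. Trib3, a pseudokinase, rose 4.79-fold from 30.9 ± 1.02 to 143 ± 5.85 FPKM, and Acot2, a mitochondrial thioesterase, 4.39-fold. Among named genes with a mean FPKM of at least 5 in the higher group and reads that are not in doubt, the largest falls were those of Mrgprf (-2.59), Dusp14 (-2.37), Txnip, which binds thioredoxin (-2.19), Gas1 (-1.87), Tmem204 (-1.85), Pml (-1.81), Angptl4 (-1.79) and Zhx1 (-1.78). Rpl10-ps1 (2.64), Rpl30-ps8 (-2.87) and the mitochondrial tRNA mt-Tf (-2.23) also met the rule, but reads of pseudogene copies and of short tRNA genes are uncertain. Chac1 lies on the plus strand of chromosome 2 at 119351229 to 119354381, and Trib3 on the minus strand of that chromosome at 152337422 to 152344032.

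By edgeR's test 4587 of 11826 genes passed, 2286 higher and 2301 lower, of which 179 rose and 276 fell at least 2-fold. The groups did not overlap in 50.7% of genes, where chance gives 10%. The call of Rpl30-ps8 (adjusted p 0.0213) was lost without untreated replicate 1 (0.0617) and without (A/R) platelet replicate 1, 2 or 3 (0.0565, 0.0629 and 0.0684). The 10 genes with most counts took 5.40% to 5.64% of counts in (A/R) platelet libraries and 4.93% to 5.16% in the others.

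Camera called 14 of 31 lists, and 6 of them also with an estimated correlation. Stress genes of ATF4 rose nearly throughout: 25 of 26 measured members passed, also adjusted over the list alone, with a median of 0.93. Chac1, Trib3 and Mthfd2, a mitochondrial folate enzyme (1.33 ± 0.050, SE), had the smallest p (list adjusted p 1.75e-44, and adjusted p = 0.000343 with an estimated correlation). Ribosome biogenesis genes rose in 27 of 29 members (also 27 adjusted over the list alone), among them Ppan (1.01) and Ncl (0.58), with an adjusted p of 4.21e-16, and adjusted p = 0.00358 with an estimated correlation. Of 20 immediate early genes 11 rose and 2 fell (12 and 2 adjusted over the list alone), with Phlda1 2.29-fold higher, Srf at 1.08 and Fosl1 at 0.88. That list had an adjusted p of 4.43e-07, and adjusted p = 0.0319 with an estimated correlation.

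Replication genes fell in 28 of 30 members (29 adjusted over the list alone), with a median of -0.59. Cdc6, which loads the replicative helicase, fell by 1.73 on the log2 scale, from 18.5 ± 1.10 to 5.36 ± 0.266 FPKM (SD, n = 3). Rrm2 (-0.89) and Mcm6 (-0.74) fell as well (list adjusted p 7.41e-22, and adjusted p = 0.000457 with an estimated correlation). Of 30 mitosis genes 17 fell and 1 rose, over all genes and adjusted over the list alone, with Mki67 at -0.66. That list had an adjusted p of 0.00371, and adjusted p = 0.0487 with an estimated correlation. Unfolded protein response genes of the endoplasmic reticulum fell in 16 of 20 members (17 adjusted over the list alone), with a median of -0.48. Examples were the chaperone genes Dnajc3 (-1.30 ± 0.048, SE) and Calr (-0.59) and the ubiquitin ligase Syvn1 (-1.0). Their list had an adjusted p of 1.17e-10, and adjusted p = 0.00331 with an estimated correlation.

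A further 8 lists were called with the preset correlation only. Ribosomal proteins rose in 28 of 35 members (31 adjusted over the list alone) with a median of 0.28 (adjusted p 0.000103, and adjusted p = 0.611 with an estimated correlation). Antioxidant genes of NRF2 rose in 10 and fell in 1 of 22 (10 and 2 adjusted over the list alone), led by Hmox1, heme oxygenase (1.62), and the cystine transporter Slc7a11 (1.41). That list had an adjusted p of 0.00395, and adjusted p = 0.0518 with an estimated correlation. Heme and iron genes, Hmox1 included, rose in 4 of 13 (4 adjusted over the list alone) at 0.0367, with adjusted p = 0.134 with an estimated correlation. Cholesterol synthesis genes fell in 12 and rose in 1 of 24 (13 and 2 adjusted over the list alone), with Stard4 (-0.64) lower, at an adjusted p of 0.00371, and adjusted p = 0.0751 with an estimated correlation. Fatty acid synthesis genes fell in 5 and rose in 2 of 13 (6 and 2 adjusted over the list alone) at 0.0219, with adjusted p = 0.298 with an estimated correlation. Growth factor receptors fell in 10 and rose in 2 of 19 (11 and 2 adjusted over the list alone), among them Pdgfrb (-0.96) and Tgfbr2 (-0.91), at 0.0109, with adjusted p = 0.309 with an estimated correlation. Interferon-stimulated genes fell in 7 and rose in 1 of 17 (8 and 2 adjusted over the list alone), with Gbp7 at -1.39, at 0.0258, with adjusted p = 0.111 with an estimated correlation. Transcripts of the mitochondrial genome fell in 8 and rose in 1 of 13 (8 and 1 adjusted over the list alone), with mt-Cytb at -0.60 and mt-Co1 at 0.42 (0.23, adjusted p 0.148, with quantile normalization), at 0.0367, with adjusted p = 0.611 with an estimated correlation. The call of the heme list was lost without platelet replicate 2 or untreated replicate 2 (0.0810, the latter). That of the mitochondrial list was lost without untreated replicate 2 or 3 or (A/R) platelet replicate 3 or 1 (0.0914, the last). Over 20 alternatives with the preset correlation, the heme list was called in 11 (camera adjusted p up to 0.295). Antioxidant and interferon-stimulated genes were each called in 16 (up to 0.271 and 0.114), and mitochondrial transcripts in 15.

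Several lists were not called as a whole but held changes in both directions. Of 21 measured genes of hypoxia and glycolysis 4 rose, Ndrg1 (1.65), Hk2, hexokinase 2 (1.31), and Vegfa (1.21) among them, and 8 fell. That list's median was -0.05 and its mean 0.07 while its test pointed up (adjusted p 0.0794). Inflammatory genes of NF-kappa B rose in 5 of 14, Ptgs2, cyclooxygenase 2 (1.76), among them, and fell in 3 (0.0680). The list of matrix enzymes rose in 4 of 15 and fell in 6 (0.365). Among its rises were Timp3 (1.89) and Plaur (1.54), which are not enzymes themselves. Angiogenic factors rose in 6 and fell in 6 of 17, Vegfd (-1.25) among the latter (0.791), and p53 targets rose in 5, with Plk2 at 0.94, and fell in 6 of 20, with Cdkn1a at -0.56 (0.788). Collagens and matrix genes rose in 5 and fell in 9 of 19, with Col3a1 at -0.90 and Col1a1 at -0.54 (0.439). TGF-beta targets rose in 8 and fell in 7 of 21, Ccn2 (-0.41) among the latter (0.878). Adjusted over the list alone the tallies were the same, except for angiogenic factors (7 and 7) and TGF-beta targets (8 and 8). Myc (0.91) rose. Tgfb1 (-0.22, adjusted p 0.0679), Ccl2 (0.11, 0.140), Cd274 (0.50, 0.108) and Mmp9 (-0.19, 0.406) did not pass edgeR's test. Tgfb1 passed in 8 of 23 alternatives, among them DESeq2, limma on log2(FPKM + 1), library totals alone and the fit without untreated replicate 3 (0.00590), and had an adjusted p of up to 0.225 over all of them. Ccl2 passed without untreated replicate 2 (0.0473), with an adjusted p of up to 0.767 over the others. Few markers of other cells could be tested. The 1 tested gene of 26 platelet transcripts, Ppbp (-1.0), and the 1 tested gene of 10 endothelial transcripts, the cadherin gene Cdh5 (-1.02), fell. Of 3 tested leukocyte genes among 24, Csf1r, the receptor of macrophage colony-stimulating factor (-0.41), fell and 2 did not pass. Of 2 tested erythroid genes among 14, Car1, carbonic anhydrase 1, fell by 7.14 (log2, adjusted p 0.0140) and 1 did not pass. With 0 to 4 counts of Car1 in (A/R) platelet libraries the size of its fall is uncertain, at -1.73 with limma on log2(FPKM + 1) and -10.53 without (A/R) platelet replicate 2. Its call was lost without (A/R) platelet replicate 3 (0.0514).

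**Figure D2:**
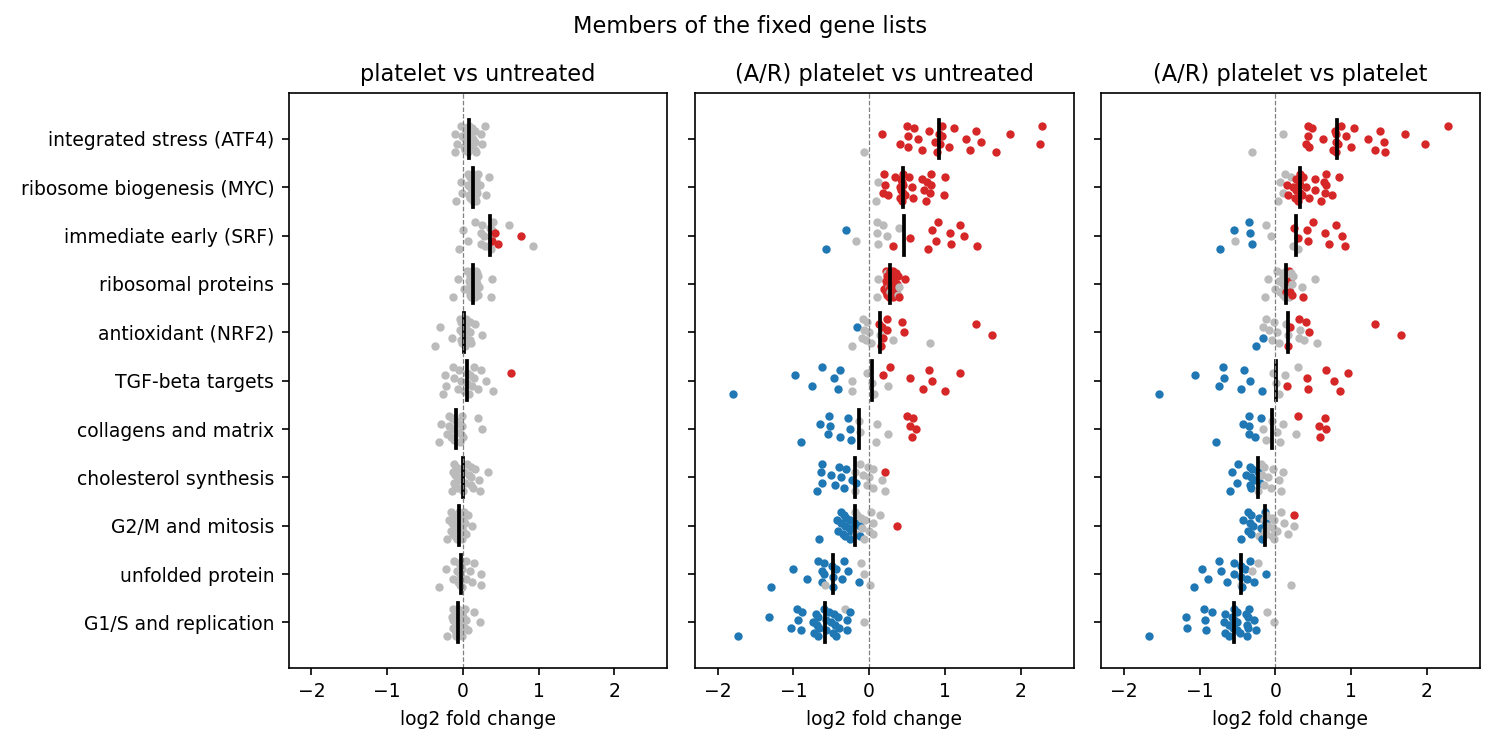
Log2 fold change (horizontal axis) of each tested member (points) of 11 of the fixed gene lists in the 3 comparisons, with red for members that rose and blue for members that fell at an adjusted p under 0.05, grey for the rest, and a black bar at the median. In (A/R) platelet against untreated libraries the median was 0.93 for ATF4 stress genes and -0.59 for replication genes, whereas with platelets it was 0.08 and -0.06.

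The direct comparison of (A/R) platelet with platelet libraries used the same (A/R) platelet libraries as the comparison with untreated ones, so that their results are not independent. Stbd1 (3.45), Angptl6 (3.37), Gadd45a (2.93), Cth (2.40), Acot2 (2.34), Trib3 (2.29), Gtpbp2 (2.22), Gdf15 (2.07) and Dennd4a (2.05) were higher with (A/R) platelets. Mrgprf (-2.71), Dusp14 (-2.45), Txnip (-2.18), Pml (-1.91), Tmem204 (-1.74), Cdc6 (-1.67), Slco4a1 (-1.60) and Gas1 (-1.59) were lower. The uncertain Rpl10-ps1 (3.01), Rpl30-ps8 (-2.66) and mt-Ty (-1.58) also met the rule. Hmox1 (1.66), Ptgs2 (1.47), Vegfa (1.21), Plaur (0.96) and Myc (0.66) were higher. Ereg, an EGF receptor ligand (-1.10), Ccn2 (-1.06), the transcription factor Twist1 (-0.97), the chemokine Cxcl5 (-0.85), Pdgfra (-0.79), Cd44 (-0.72) and Tgfb1 (-0.42) were lower.

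By edgeR's test 4052 genes passed, of which 2028 were lower and the rest higher, and 138 rose and 202 fell at least 2-fold. The groups did not overlap in 49.0% of genes, where chance gives 10%. The call of Rpl30-ps8 (adjusted p 0.0318) was lost in 11 of 23 alternatives, among them those without platelet replicate 2 (-1.30, adjusted p 0.136) or without (A/R) platelet replicate 1, 2 or 3 (0.0765, 0.0868 and 0.0945). Car1 (-6.05, adjusted p 0.0320) was lower too, but its call was lost in 12 of 22 alternatives, among them limma on log2(FPKM + 1) (-0.88, 0.261) and the fits without platelet replicate 2 (-3.85, 0.128) or (A/R) platelet replicate 1, 2 or 3 (0.0905, 0.0794 and 0.0988). Camera called 9 of 31 lists, and 4 also with an estimated correlation. Stress genes of ATF4 rose in 24 of 26 members (25 higher and 1 lower adjusted over the list alone), Chac1 (1.98) and Aldh1l2 (1.38) among them, with an adjusted p of 4.65e-45, and adjusted p = 0.000338 with an estimated correlation. Ribosome biogenesis genes rose in 24 of 29 (25 adjusted over the list alone) at 1.76e-10, and adjusted p = 0.0113 with an estimated correlation. Replication genes fell in 28 of 30 (28 adjusted over the list alone) at 2.25e-21, and adjusted p = 0.000488 with an estimated correlation. Unfolded protein response genes fell in 16 of 20 (17 adjusted over the list alone), Dnajc3 (-1.07) among them, at 1.48e-11, and adjusted p = 0.00254 with an estimated correlation. The other 5 called lists were not called with an estimated correlation. Cholesterol synthesis genes fell in 13 of 24 (14 adjusted over the list alone), Stard4 (-0.57) among them, at 0.00110 (adjusted p = 0.0613 with an estimated correlation). Growth factor receptors fell in 9 and rose in 1 of 19 (9 and 1 adjusted over the list alone) at 0.00199 (adjusted p = 0.241 with an estimated correlation). Antioxidant genes rose in 7 and fell in 2 of 22 (7 and 2 adjusted over the list alone) at 0.00318 (adjusted p = 0.0610 with an estimated correlation). Heme and iron genes rose in 4 of 13 (5 higher and 1 lower adjusted over the list alone) at 0.0289 (adjusted p = 0.116 with an estimated correlation). Mitosis genes fell in 13 and rose in 1 of 30 (14 and 1 adjusted over the list alone), Mki67 (-0.45) among them, at 0.0397 (adjusted p = 0.116 with an estimated correlation). The mitosis call was lost without platelet replicate 3 or (A/R) platelet replicate 1 (0.0680, the latter). Over 20 alternatives with the preset correlation, antioxidant genes were called in 16 (camera adjusted p up to 0.160). Heme and iron genes were called in 14 (up to 0.177) and mitosis genes in 17. Immediate early genes were not called (0.0784), with 10 of 20 higher and 5 lower.

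Most genes called with platelets also changed with (A/R) platelets. Of the 31, 26 passed against untreated in both treatments: 18 rose in both, 4 fell in both and 4 went opposite ways. Of all tested genes, 38.8% passed for (A/R) platelet against untreated. Independent lists would share 4.83 rises and 1.17 falls. Among the shared rises, Plaur reached 30.5 ± 0.763, 45.1 ± 3.94 and 85.4 ± 0.895 FPKM (SD, n = 3) in untreated, platelet and (A/R) platelet libraries. Hbegf reached 14.7 ± 0.320, 20.4 ± 0.457 and 23.4 ± 0.461. In the direct test between the treatments, 28 of the 31 passed, against 34.3% of all tested genes. The 31 were called with the same platelet libraries and the same fitted spread that this test uses. A high share is therefore partly built in, and 34.3% is no fair reference for it. Across the 11826 genes, which are not independent replicates, the log2 fold changes of the treatments had a Pearson correlation of 0.356 and a Spearman correlation of 0.377. Simulated unchanged groups that share the untreated libraries had a mean Pearson correlation of 0.498. They had the same direction in 66.7% of genes, against 64.1% observed. A mean of 0.02 simulated calls were shared in the same direction, but these groups had means of only 0.12 and 0.10 calls to share. The observed covariance was 0.0537 against 0.0329 in the simulation, a difference of 0.0208. With 3 untreated libraries the controls cannot be split, and part of the shared calls may come from the shared controls.

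**Figure D3:**
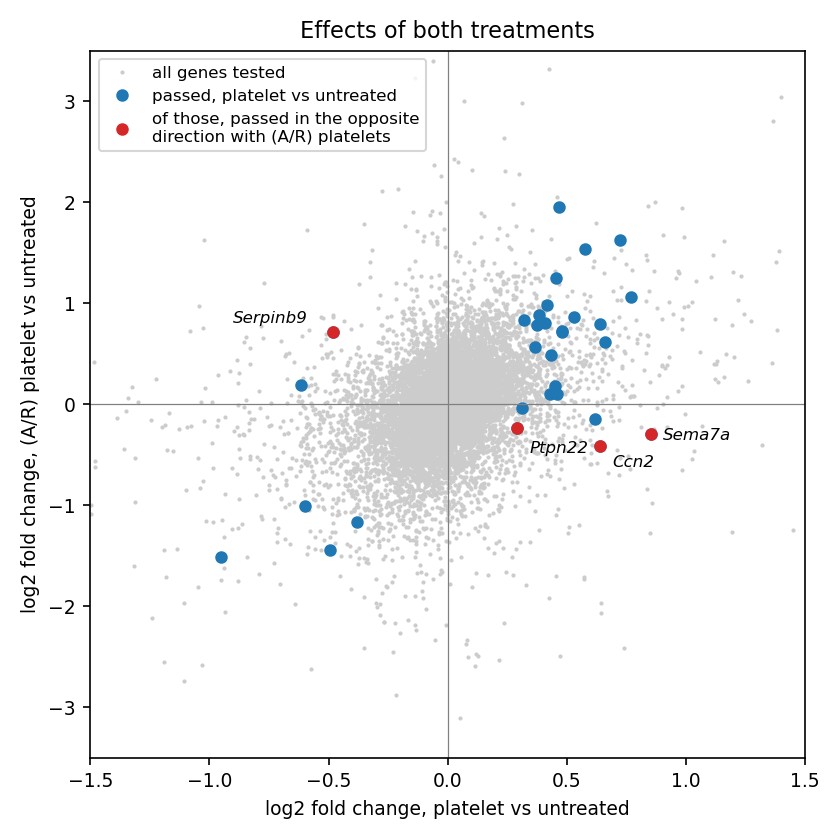
Log2 fold change against untreated libraries with platelets (horizontal axis) and with (A/R) platelets (vertical axis) for all tested genes (grey), the 31 genes called with platelets (blue), and the 4 of those called in the opposite direction with (A/R) platelets (red, named). A further 54 genes lie outside the axes.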

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

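The tests on what (A/R) platelets lack and on labelled hours were chosen only after the result was seen. The 4 genes below passed against untreated libraries in opposite directions with the 2 treatments, and their treatment effects differed in edgeR's direct test. That test takes the difference of the 2 effects in the same fit. Genes chosen for opposite calls all but have to pass it, so its p adds no separate evidence. Ccn2 was 0.64 ± 0.059 (log2, SE) with platelets and -0.41 ± 0.059 with (A/R) platelets, a difference of -1.06 ± 0.060 (adjusted p 4.41e-06). Sema7a was 0.85 ± 0.089 and -0.29 ± 0.089, a difference of -1.14 ± 0.089 (2.65e-05). Ptpn22, a phosphatase gene, was 0.29 ± 0.041 and -0.24 ± 0.041, a difference of -0.53 ± 0.042 (2.78e-05). Serpinb9 went the other way, with -0.48 ± 0.053 and 0.72 ± 0.053, a difference of 1.203 ± 0.053 (1.44e-06). Ptpn22, and Sema7a and Serpinb9 with (A/R) platelets, were named after their values were seen.

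If (A/R) platelets merely lacked all that platelets supply, (A/R) platelet libraries would stay at the untreated level. Instead 4561 of the 11795 genes not called with platelets passed there, which argues against that. The count cannot tell whether (A/R) platelets lack only a part, since they could still act through the rest. It also leaves out the 4 genes themselves. What differs with (A/R) platelets was not tested. If labelled hours, taken as true times, drove the differences, the 4 genes would move by 0.326 (log2 CPM) per hour within groups in the direction of their difference, but their mean slope there was 0.031 ± 0.019 (SE). The fall of Sema7a with (A/R) platelets was lost in 7 of 23 alternatives, among them those without untreated replicate 2 or 3 or (A/R) platelet replicate 2 or 3 (adjusted p 0.0920, 0.0709, 0.0937 and 0.0985). The rise of Ptpn22 with platelets was lost in 16 of 23, and among the 9 fits without 1 library (adjusted p up to 0.138) it was kept only without (A/R) platelet replicate 2. The fall of Serpinb9 with platelets was lost in 2 of 23 alternatives (adjusted p up to 0.0636), among them the 6 libraries of that comparison alone (0.0519).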

How the results depend on the processing

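DESeq2, limma on log2(FPKM + 1), counts divided by 4 and library totals alone were chosen after the data were seen. For platelet against untreated, the 31 genes became 18 in the 6 libraries of the comparison (fewer samples), 222 with DESeq2, and 0 at a change of at least 2-fold. Without 1 library in turn the count was 18 to 26. The cause of the DESeq2 difference was not tested. DESeq2 made more false calls on simulated data, but these were drawn from edgeR's own fit, which may favour edgeR. With a replicate block edgeR called 0 genes (1337 at an unadjusted p under 0.05), so each named platelet call was lost there. Same-numbered libraries share only a number: their deviations from the group means correlated at -0.025 to 0.050, and 0 of 9 libraries correlated best with their own number in both other groups. With the block, 4171 and 3725 genes passed in the (A/R) comparisons, and 9, 13 and 12 lists were called. At a change of at least 2-fold, 455 and 340 genes passed for (A/R) platelet against untreated and against platelet. Elsewhere their counts stayed within 1.5 times the main ones, between 3084 and 4862. Higher genes made up 49.8% of calls for (A/R) platelet against untreated, 41.0% with library totals alone and 40.9% with limma on log2(FPKM + 1).

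With an estimated correlation, 2, 6 and 4 lists were called rather than 12, 14 and 9. For platelet against untreated, interferon-stimulated, replication and mitosis genes had estimated correlations of -0.028, -0.010 and -0.0088. These lie below the preset 0.01, yet the camera adjusted p rose to 0.165, 0.20 and 0.169. That argues against a higher correlation between members as the cause for these lists. Ribosomal proteins had 0.652, and the cause was otherwise not tested. Without 1 library in turn, 7 to 11 lists were called for platelet against untreated, the fewest without platelet replicate 2. Without a filter 15 of 36 lists were called for (A/R) platelet against platelet, against 9 of 31 in the main fit. The set of lists tested thus differed, and the cause was otherwise not tested. The correlation of the effects of both treatments was 0.252 to 0.490 without 1 library in turn and 0.487 without a filter, where the cause was not tested.

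No named gene changed sign past the threshold. Over all alternatives, 14 of 40 named genes kept their side of the threshold for platelet against untreated. These 14 were all genes not called in the main fit, since each named platelet call was lost with the replicate block. Of the 21 named platelet calls, 11 held in all 9 fits without 1 library. In the other comparisons, 62 of 68 kept their side for (A/R) platelet against untreated and 39 of 41 for (A/R) platelet against platelet. In simulated libraries of these depths, 24% of changes of 0.3 (log2) and 68% of those of 0.5 were recovered for platelet against untreated. What depth adds to that was not simulated.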

Other observations

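The pathway tests, the splits of the libraries, and the tests on platelet RNA, on counts that overstate fragments and on endoplasmic reticulum stress were chosen only after the results were seen. In the pathway terms of the deposited annotation, camera called 14 of 285 terms for (A/R) platelet against untreated, 8 higher and 6 lower. Ribosome biogenesis rose in 47 and fell in 2 of 71 genes (adjusted p 1.02e-11, and adjusted p = 0.0255 with an estimated correlation), the only 1 of the 14 called with both correlations. Aminoacyl-tRNA biosynthesis rose in 23 and fell in 3 of 44 genes (4.66e-06, and adjusted p = 0.346 with an estimated correlation), and the one carbon pool by folate rose in 9 and fell in 2 of 16 (0.0133, and adjusted p = 0.396 with an estimated correlation). Ferroptosis genes rose in 11 and fell in 1 of 32 (0.0392, and adjusted p = 0.396 with an estimated correlation). DNA replication genes fell in 25 and rose in 2 of 35 (4.66e-06, and adjusted p = 0.161 with an estimated correlation), and mismatch repair genes fell in 12 and rose in 1 of 22 (0.0133, and adjusted p = 0.396 with an estimated correlation). With platelets 7 terms were called, all higher, and 0 of them with both correlations.

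Csf1r, usually a gene of macrophages, held 1994 to 2875 CPM in all 9 libraries, while the leukocyte gene Ptprc held 0 to 12 counts and Tyrobp 0 to 17 counts per library. Lyz2 ranged from 12 to 152 counts in untreated, 21 to 347 in platelet and 9 to 82 in (A/R) platelet libraries. Car1 held 63, 186 and 255 counts in untreated libraries, 39, 217 and 0 in platelet libraries, and 0, 4 and 0 in (A/R) platelet libraries.

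Stress genes of ATF4 were higher in (A/R) platelet libraries with a list median of 0.93. For a difference in depth, a median under 0.5 was predicted once all libraries were thinned to 1 total, and it stayed at 0.92. That was no test of depth, since thinning by 1 factor per library leaves fold changes of well-counted genes about as they were. Removal of trends over GC content and transcript length left 0.94. Those trends explained 0.614% of the variance over genes and so had little to remove. If labelled hours, taken as true times, drove the rise, the list would climb by 0.308 (log2 CPM) per hour within groups, but its mean slope there was -0.027 ± 0.012 (SE). A general endoplasmic reticulum stress response still under way at harvest would raise the unfolded protein list, whose median was -0.48. Hspa5 was at -0.44 and Herpud1 at -0.07 (edgeR adjusted p 0.639), while Atf4 itself was at 0.97, all chosen after their values were seen. Without earlier time points, a response that had passed by harvest would go unseen. What raised the ATF4 genes stays open, since no other biological explanation was tested.

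Immediate early genes were higher in platelet libraries with a list median of 0.36. RNA from the added platelets would raise platelet transcripts, whose summed CPM in platelet libraries was 0.940 times that of untreated ones. That sum includes transcripts already present in untreated libraries, so small amounts of platelet RNA would go unseen. Gp5, chosen after its values were seen, had 0 counts in untreated libraries and 8, 6 and 4 in platelet libraries. If the call rested on counts that overstate fragments, it would be lost in limma on log2(FPKM + 1), which takes the spread from replicates rather than from the size of counts, and the camera adjusted p there was 5.35e-15. A division of all counts by 4 was no test of this, since it is 1 factor for all libraries. The adjusted p ranged from 5.1e-22 to 3.41e-14 over all alternatives with the preset correlation. A single library out of place would bring the median under 0.1, and its lowest value without 1 of the 6 libraries was 0.32. What kept these genes higher at harvest was not tested.

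In each comparison the 6 libraries allow 10 splits, and 1 of the 10, the real one, gave as many calls as observed. The counts were 31 for platelet against untreated, 4587 for (A/R) platelet against untreated and 4052 for (A/R) platelet against platelet, against at most 3 calls in any other split of each. With 10 splits the share cannot go below 0.1, so the design cannot give a share under 0.05. Each other split mixes libraries of both groups, so any real difference adds to the spread there and leaves few calls. The low counts of the other splits are therefore no measure of chance.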
